A study of Mus musculus with 67 samples.

How the data were processed

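RNA was measured by Smart-seq2 sequencing of small pools of cells from wild-type mouse embryos carrying a reporter driven by the Pdgfra promoter, per the labels' protocols. The authors' deposited table gives TPM (length-scaled transcript shares) for 25006 genes in 67 libraries of 23 groups. Per the submitters' processing notes, HISAT2 2.2.1, StringTie 2.2.1 and Cufflinks were used with the mm10 build. The role and order of these tools, the Cufflinks version, the annotation and any use of strand are not given. Overlapping and near-identical genes thus cannot be told apart with certainty. Column sums ran from 985702 to 996469, and all columns matched a sample by title. TPM keeps no depth, so the number of reads behind a value and its counting error are unknown. Since a value of exactly 0 can be a failed estimate, such genes are described as listed at 0 and no fold is given against a group at 0.

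Values were analysed as log2(TPM + 1), a scale that understates the change of low genes. Genes of at least 1 TPM in at least 3 libraries were kept (15567). Group means of all 67 libraries were fitted together with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend), so that groups of 2 to 4 libraries share 1 estimate of spread per gene. p-values were adjusted by the Benjamini-Hochberg method over all genes kept. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Unless another test is named, every adjusted p of a gene is from limma, and levels are means ± SD of TPM with log2 differences ± standard error. Figures were drawn with python 3.11.15.

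The 28 gene lists covered core, naive and formative pluripotency, primitive, visceral secretory, distal and anterior visceral and parietal endoderm, trophectoderm, extra-embryonic ectoderm, giant cells, uterine stroma, and blood. They also covered Polycomb, H3K4 methyltransferases, H3K4 and H3K27 demethylases, DNA methylation, developmental regulators, glycolysis, oxidative phosphorylation, hypoxia, immediate early and heat shock genes, p53 targets, cholesterol synthesis, mitosis, FGF and ERK targets, Nodal, BMP targets and polarity. Of their 383 symbols 381 were in the table. Lists with at least 5 kept members were tested with camera with an estimated correlation, adjusted over the lists of a comparison. Every adjusted p printed for a list is from that test unless stated. Of 442 list results, 84 differed in sign between median, mean and test, and 0 of these were called.

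The lists, designs, alternatives and rule for naming genes were fixed before the data were examined. The rule took up to 3 called members per list and direction by size, the 5 called genes per direction of largest difference among those whose libraries did not overlap, 7 lineage genes, and up to 2 uncalled members per list of highest mean TPM. Predicted and Y-linked genes and Xist were left out of the top genes. A GRCm38 annotation gave positions for 15203 of the genes kept. The fit was tested on simulated data. With 100 of 15567 genes changed by 1.5 log2 and another 100 by 3, it recovered 69% of the former in the TE and ICM groups, 80% in the TGC and ExE groups and 71% in the E5.5 Epi groups, and 98%, 100% and 98% of the latter. Of all calls 7.73%, 4.76% and 8.65% were false, which unequal group spread may change. Alternatives were a pseudocount of 0.1 TPM, no filter, quantile normalization, median-ratio scaling, array weights, fits of only the groups compared, a replicate block, no minimum difference, and each library left out in turn.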

Results

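The data comprised 67 wild-type mouse RNA-seq libraries in 23 groups, each a tissue of the blastocyst or early post-implantation embryo at 1 labelled age. The inner cell mass (ICM) was sampled at E3.5 and the trophectoderm (TE) at E3.5 and E4.5. The epiblast (Epi) was sampled from E4.5 to E5.5 and the primitive endoderm (PrE) from E4.5 to E5.25. The visceral endoderm (VE) was sampled at E5.5, the extra-embryonic ectoderm (ExE) and trophoblast giant cells (TGC) at E4.75 and E5.5. Groups held 3 libraries each, except 2 in Epi, ExE and VE_Epi of E5.5 in vivo and 4 in TGC of E5.5 in vitro. The labels of the E5.5 groups state whether embryos were cultured (in vitro) or not (in vivo). Epi of E5.0 and E5.25 exists with and without an in vivo suffix, and whether the unsuffixed groups were cultured is not stated. Each library was amplified from few cells, so PCR copies cannot be separated from molecules, and no counting interval can be given without depth. Between 8423 and 12644 genes reached 1 TPM in a library. The 12644 were in Epi replicate 1 of E4.5, with 3307 genes at 0 against 13659 and 12723 in replicates 2 and 3. Within groups, Pearson correlations of log2(TPM + 1) across genes ran from 0.858 to 0.994, with a median of 0.984. The labels do not say that libraries of a group came from separate embryos, so p-values measure only the spread between these libraries, which may be technical.

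Marker levels followed the group labels in most groups. Pdgfra, whose promoter drives the reporter used for sorting and which encodes a growth factor receptor of the primitive endoderm, lies at chromosome 5, 75152292 to 75198215. It was 17.4 ± 2.51 TPM in PrE and 2.15 ± 1.12 TPM in Epi of E4.75 (n = 3 each). Nanog (chromosome 6, 122707489 to 122714633), a pluripotency factor, was 404 ± 19.9 TPM in ICM and 250.3 ± 63.3 TPM in Epi of E4.5, and 7.22 ± 2.58 TPM in Epi of E4.75. Cdx2 (chromosome 5, 147300805 to 147307270), a trophectoderm factor, was 30.4 ± 4.99 TPM in TE of E3.5 and 3.58 ± 1.77 TPM in TE of E4.5. Eomes (chromosome 9, 118478212 to 118486132), a T-box factor of trophoblast and endoderm, was 100.2 ± 7.98 TPM in ExE of E4.75. ExE of E4.75 also held Sox17 at 17.0 ± 0.987, Ttr at 58.0 ± 3.02, Nanog at 16.2 ± 1.34 and Pou5f1 at 24.1 ± 1.80 TPM (n = 3), genes of other lineages. All positions are on GRCm38, the assembly that mm10 names. Rn45s, the precursor of ribosomal RNA, took 22.0% ± 3.17 of the TPM in Epi of E4.5 and 17.6% ± 2.91 in PrE of E4.5 (SD, n = 3 each). It took 9.33% ± 1.60 in Epi of E5.0 in vivo. Actb ranged from 0.0528% ± 0.00232 in Epi of E5.0 in vivo to 13.3% ± 3.11 in VE_ExE in vivo. Contrasts of these groups with others compare libraries of different composition.

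**Figure D1:**
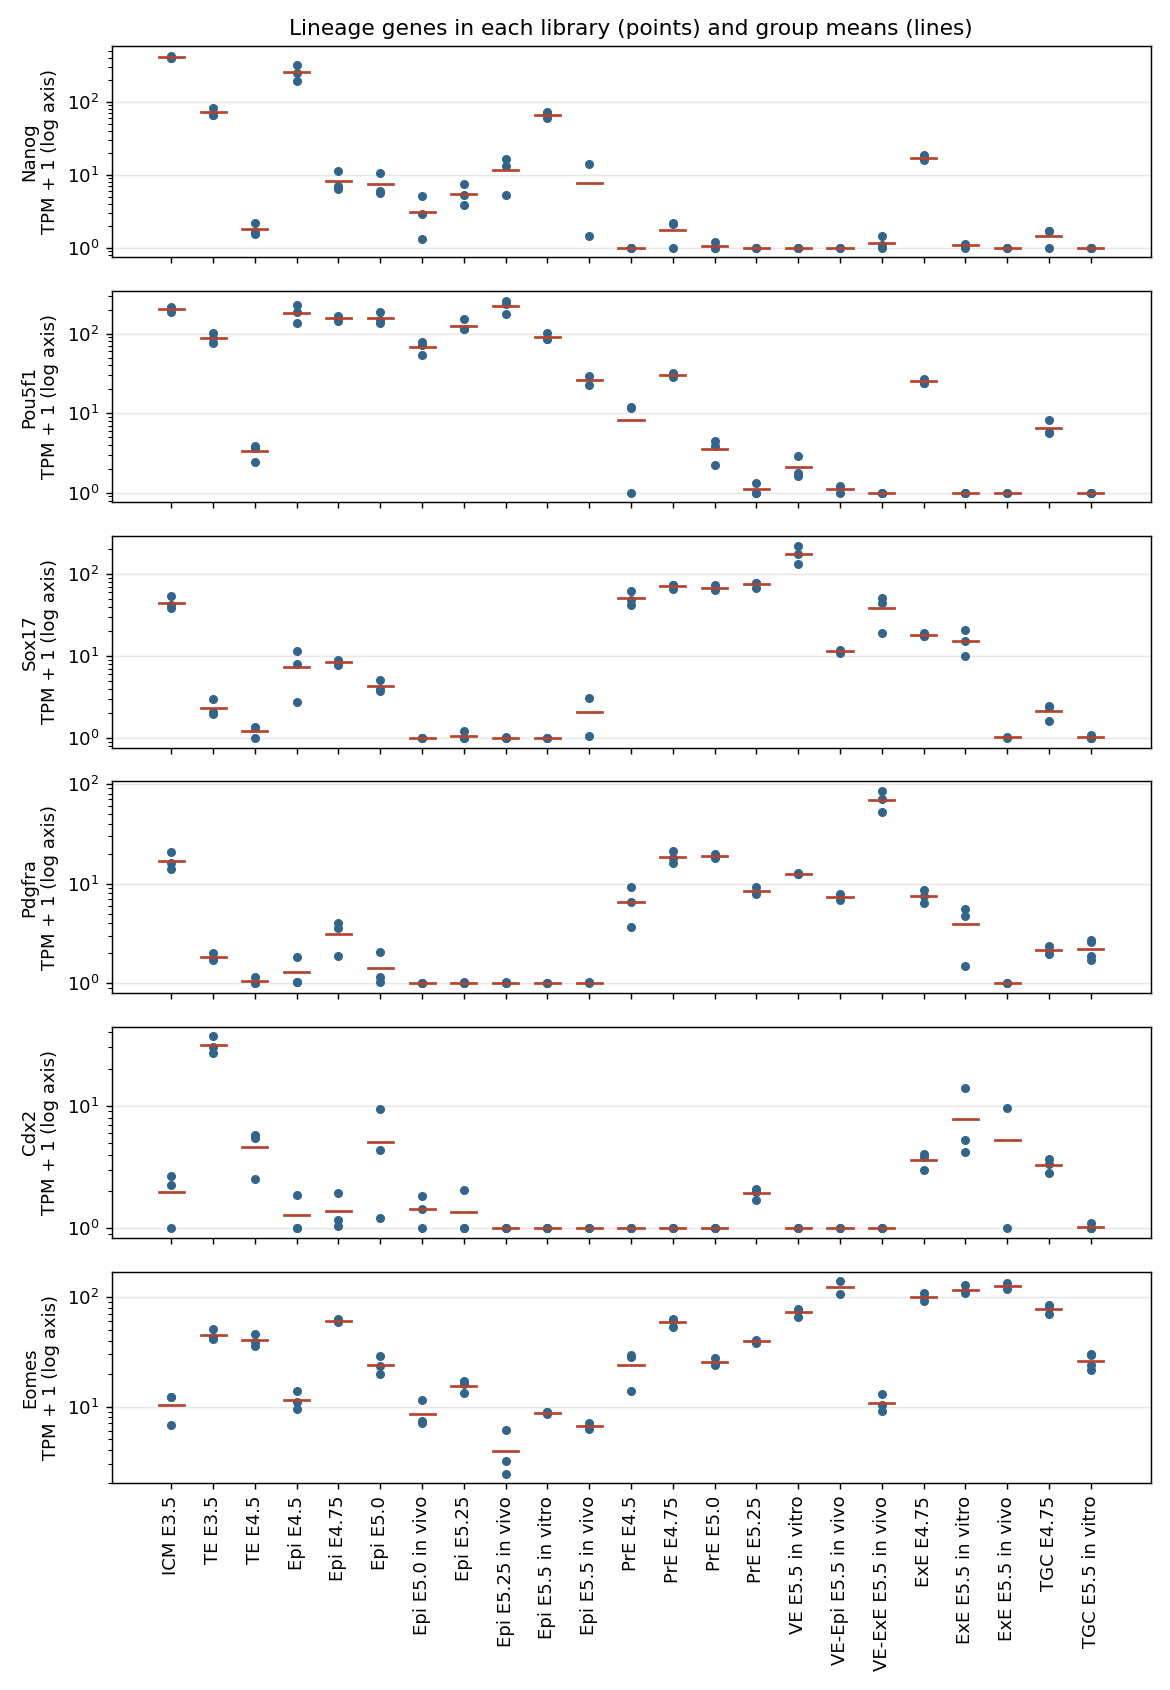
Each point is 1 library's TPM + 1 on a log axis for Nanog, Pou5f1, Sox17, Pdgfra, Cdx2 and Eomes, with the 23 groups on the horizontal axis and short lines at the group means. Nanog averages 404 TPM in ICM of E3.5 and Cdx2 30.4 TPM in TE of E3.5.

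**Figure D2:**
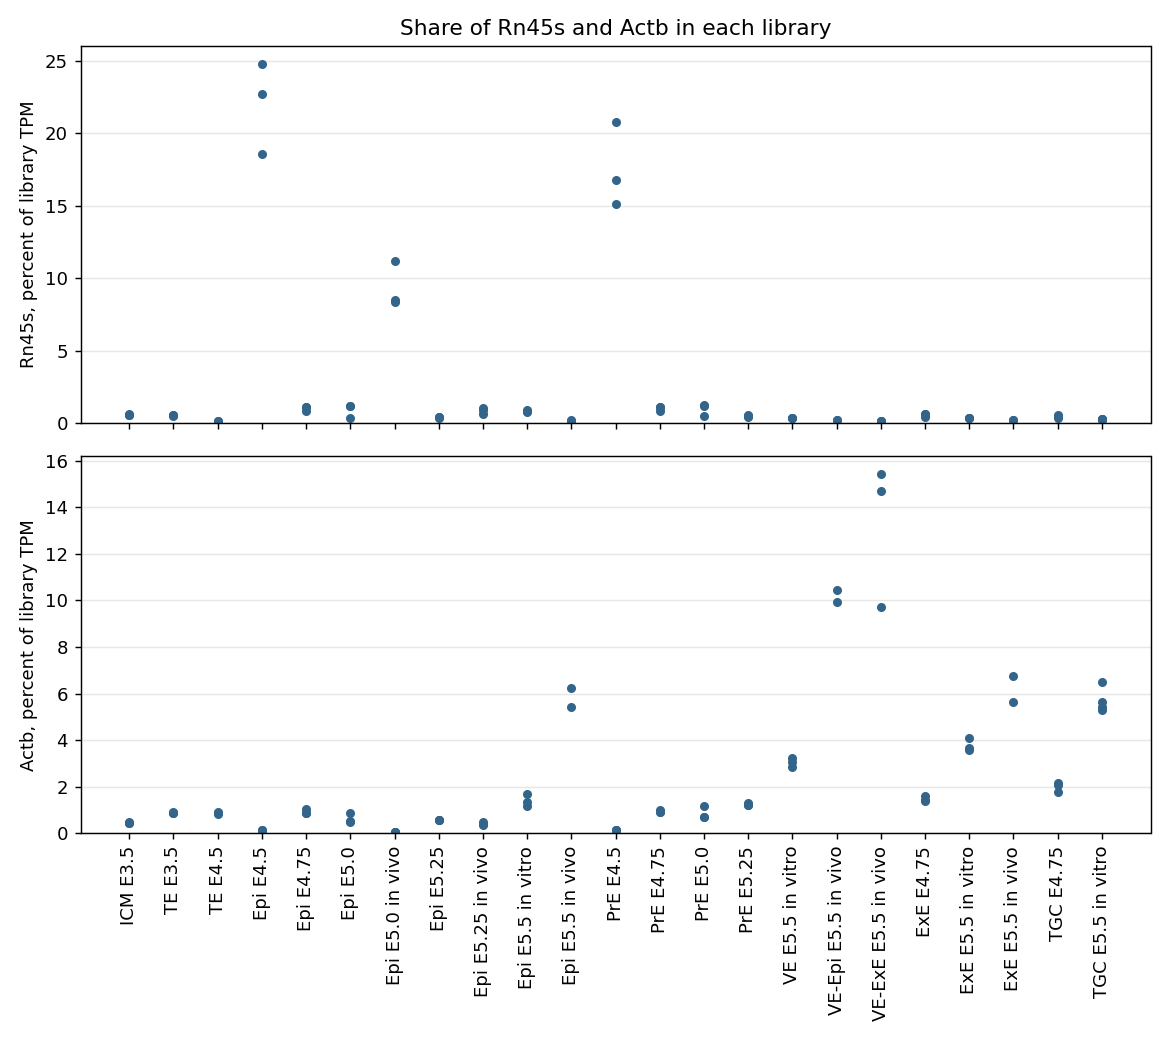
Each point is 1 library's percent of its summed TPM taken by Rn45s (upper panel) or Actb (lower panel), by group. Rn45s averages 22.0% in Epi of E4.5 and Actb 13.3% in VE_ExE of E5.5 in vivo.

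The first comparison asks which transcripts separate the trophectoderm from the inner cell mass at E3.5 (n = 3 each). Keratin and trophectoderm factor transcripts were higher in TE. Krt18 (chromosome 15, 102028180 to 102032027), a keratin of simple epithelia, rose to 4904 ± 110.1 against 133 ± 8.67 TPM in ICM, a log2 difference of 5.19 ± 0.15 (adjusted p = 1.6e-32). Its processed copies in the genome make that level uncertain. Cdx2 was 30.4 ± 4.99 against 0.975 ± 0.873 TPM (log2 4.10 ± 0.48, adjusted p = 9.4e-10). Pluripotency factors were lower: Nanog was 70.1 ± 8.81 against 404 ± 19.9 TPM (log2 -2.52 ± 0.43, adjusted p = 8.2e-06), and Fgf4, a growth factor secreted by the pluripotent cells, was 0.472 ± 0.208 against 32.6 ± 2.39 TPM (log2 -4.52 ± 0.31, adjusted p = 2.0e-17). Of 15567 genes tested with limma, 922 were higher and 1186 lower in TE.

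Of the 14 trophectoderm genes tested, 12 rose and 0 fell, the same 12 when adjusted over the list alone (camera with an estimated correlation, adjusted p = 1.9e-09). Among them were the tetraspanin Tspan8 (776 ± 31.3 against 18.9 ± 2.66 TPM, log2 5.29 ± 0.51) and the helix-loop-helix factor Id2 (742 ± 20.3 against 21.5 ± 1.45 TPM, log2 5.05 ± 0.22). Of 10 extra-embryonic ectoderm genes 3 rose and 2 fell (adjusted p = 0.24): the ETS factor Elf5 (12.9 ± 3.63 against 0.357 ± 0.328 TPM, log2 3.35 ± 0.24), Wnt7b (21.7 ± 5.06 against 1.25 ± 0.938 TPM, log2 3.42 ± 0.56) and Eomes (44.3 ± 5.21 against 9.34 ± 3.14 TPM, log2 2.18 ± 0.24) rose and Bmp4 fell (0.610 ± 0.425 against 83.0 ± 9.42 TPM, log2 -5.74 ± 0.61). The naive pluripotency list had 0 risen, 9 fallen and 6 uncalled of 15, with 9 fallen when adjusted over the list alone (adjusted p = 1.3e-05). It included the transcriptional regulator Prdm14 (0.416 ± 0.721 against 20.6 ± 3.04 TPM, log2 -4.03 ± 0.43) and the kinase co-activator Tcl1 (10.5 ± 1.26 against 198 ± 9.34 TPM, log2 -4.12 ± 0.31). In the core pluripotency list 5 of 10 fell, also 5 when adjusted over the list alone (adjusted p = 0.0088): the Nodal co-receptor gene Tdgf1 (23.5 ± 1.30 against 1050.0 ± 32.3 TPM, log2 -5.43 ± 0.21) and Sox2 (0.456 ± 0.345 against 10.4 ± 2.74 TPM, log2 -2.97 ± 0.39) were among them. Pou5f1, which encodes OCT4, was 87.3 ± 13.2 against 202 ± 15.3 TPM (log2 -1.21 ± 0.40, adjusted p = 0.026). That call was lost without ICM replicate 2 (limma adjusted p = 0.075), ICM replicate 3 (0.072), TE replicate 1 (0.10) or TE replicate 2 (0.064). It was also lost under median-ratio scaling (0.065) and with a pseudocount of 0.1 TPM (0.33). Dppa5a (11296 ± 729 against 16811 ± 202 TPM, log2 -0.58 ± 0.09), Dppa3 (6203 ± 264 against 6091 ± 181 TPM, log2 0.03 ± 0.46), Tfap2c (46.8 ± 5.06 against 53.2 ± 4.61 TPM, log2 -0.18 ± 0.53) and Gata6 (23.6 ± 2.48 against 18.1 ± 4.35 TPM, log2 0.39 ± 0.33) were not called.

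Primitive endoderm genes were lower in TE for 10 of 20 and higher for 2, with 3 higher and 10 lower when adjusted over the list alone, and the list was not called (adjusted p = 0.066). Sox17 (1.34 ± 0.557 against 43.7 ± 7.80 TPM, log2 -4.27 ± 0.34), Pdgfra (0.818 ± 0.155 against 15.9 ± 3.56 TPM, log2 -3.20 ± 0.33) and the matrix gene Sparc (19.2 ± 3.27 against 207 ± 7.42 TPM, log2 -3.37 ± 0.16) fell, while the endocytic adaptor gene Dab2 rose (508 ± 15.6 against 19.2 ± 3.38 TPM, log2 4.66 ± 0.29). Of the glycolysis list 3 rose and 6 fell of 16 (adjusted p = 0.81). The glucose transporter Slc2a3 rose (135 ± 13.5 against 15.7 ± 1.86 TPM, log2 3.03 ± 0.29). Ldha, lactate dehydrogenase, fell (3.51 ± 1.25 against 42.5 ± 3.24 TPM, log2 -3.30 ± 0.12). In the epithelial polarity list 3 rose and 2 fell (adjusted p = 0.57), the apical gene Crb3 being 152 ± 9.44 against 7.72 ± 1.01 TPM, log2 4.14 ± 0.41. The hypoxia response list had 2 risen and 3 fallen of 10 (adjusted p = 0.985). Other large differences were the galectin Lgals1 (1728 ± 79.7 against 32.1 ± 0.724 TPM, log2 5.70 ± 0.26), the ceramidase Acer1 (42.3 ± 6.85 against 0.0163 ± 0.0282 TPM, log2 5.40 ± 0.17) and the ETS factor Etv5 (0.818 ± 0.502 against 39.8 ± 4.83 TPM, log2 -4.52 ± 0.40). In a fit of these 6 libraries alone camera called 0 of 26 lists, with 5 at an unadjusted p under 0.05.

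The lineage split within the ICM was compared at E4.5, with cells separated with the aid of the Pdgfra reporter (n = 3 each). Pdgfra itself was 5.52 ± 2.80 against 0.296 ± 0.481 TPM (log2 2.29 ± 0.33, adjusted p = 7.3e-08). The proteoglycan gene Srgn (2515 ± 161 against 3.75 ± 2.30 TPM, log2 difference 9.19 ± 0.38, adjusted p = 1.6e-26) and the endocytic receptor gene Cubn (539 ± 179 against 1.93 ± 2.98 TPM, log2 difference 7.96 ± 0.32, adjusted p = 4.3e-27) were also higher. Nanog was listed at 0 against 250.3 ± 63.3 TPM in Epi (adjusted p = 1.2e-21), and Pou5f1 (chromosome 17, 35506018 to 35510772) was 7.17 ± 6.21 against 181 ± 46.0 TPM (log2 -5.11 ± 0.40, adjusted p = 1.8e-15). limma called 1823 genes higher and 2627 lower in PrE, with an all-gene median of -0.20 log2, -0.01 after quantile normalization.

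The primitive endoderm list had 19 of 20 genes risen and 0 fallen, and 19 when adjusted over the list alone (camera adjusted p = 3.3e-09). Dab2 was 1961 ± 519.7 against 4.13 ± 2.29 TPM, log2 8.63 ± 0.29, the endoderm factor Sox17 49.9 ± 9.97 against 6.41 ± 4.39 TPM, log2 2.99 ± 0.34 and Gata6, which specifies this lineage, 14.9 ± 4.30 against 0.776 ± 1.02 TPM, log2 3.27 ± 0.33. Of the visceral endoderm secretory list 9 of 16 rose and 1 fell (adjusted p = 0.0032), with the thyroxine carrier Ttr (113 ± 7.91 against 0.522 ± 0.904 TPM, log2 6.38 ± 0.21) and the apolipoprotein Apoa1 (261 ± 22.8 against 1.47 ± 2.02 TPM, log2 7.04 ± 0.51). The distal and anterior visceral endoderm list had 7 risen of 11 (adjusted p = 0.0023), including the WNT inhibitor Dkk1 (75.4 ± 4.53 against 0.170 ± 0.294 TPM, log2 6.06 ± 0.26) and the homeobox gene Hhex (100.1 ± 13.2 against 2.76 ± 1.87 TPM, log2 4.85 ± 0.49). Of the cholesterol biosynthesis list 11 of 18 rose and 0 fell, and 12 rose when adjusted over the list alone (adjusted p = 0.0032). The enzymes Msmo1 (779.9 ± 118 against 122 ± 19.8 TPM, log2 2.67 ± 0.20), Dhcr7 (32.8 ± 5.40 against 4.39 ± 1.88 TPM, log2 2.70 ± 0.33) and Mvd (285 ± 32 against 49.7 ± 15.6 TPM, log2 2.53 ± 0.53) were among them. The gastric protease gene Pga5 (1315 ± 68.3 against 2.55 ± 3.79 TPM, log2 9.10 ± 0.42) was also higher.

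Naive pluripotency genes fell in 14 of 15 cases, 14 when adjusted over the list alone (adjusted p = 1.8e-10), and core pluripotency genes in 8 of 10 (adjusted p = 4.8e-04). Tdgf1 was 0.480 ± 0.536 against 373 ± 68.4 TPM, log2 -8.03 ± 0.21, the nuclear receptor Nr0b1 1.63 ± 1.41 against 458 ± 80.8 TPM, log2 -7.64 ± 0.50 and Fgf4 0.0264 ± 0.0457 against 31.8 ± 6.91 TPM, log2 -4.98 ± 0.31. Gdf3, a TGF-beta ligand, was listed at 0 against 103 ± 9.19 TPM (adjusted p = 7.4e-23). Of the FGF and ERK target list 6 fell and 1 rose of 8 (adjusted p = 0.026), with the phosphatase Dusp6 at 0.119 ± 0.206 against 54.2 ± 11.8 TPM, log2 -5.62 ± 0.21 and Etv5 at 10.7 ± 10.7 against 115 ± 23.1 TPM, log2 -3.96 ± 0.40. The trophectoderm list fell in 9 of 14 (adjusted p = 0.0021): Cldn4 was listed at 0 against 40.2 ± 22.3 TPM and Tspan8 listed at 0 against 61.6 ± 30.7 TPM. Of 29 Polycomb genes 10 fell and 5 rose (adjusted p = 0.59). Phc1 was 0.83 ± 1.44 against 332 ± 30.9 TPM, log2 -7.78 ± 0.40 and Kdm2b 2.04 ± 0.650 against 96.9 ± 20.8 TPM, log2 -5.01 ± 0.33. Of 9 H3K4 and H3K27 demethylases 6 fell (adjusted p = 0.13), among them Kdm5b (3.02 ± 1.88 against 80.1 ± 29.5 TPM, log2 -4.42 ± 0.24). The DNA methylation list was called lower (4 fell and 2 rose of 9, adjusted p = 0.04), with Tet1 (9.38 ± 2.99 against 93.3 ± 21.6 TPM, log2 -3.19 ± 0.26) and the cofactor Dnmt3l (171 ± 9.62 against 859.5 ± 88.2 TPM, log2 -2.32 ± 0.39). Klf5 (26.0 ± 5.40 against 34.9 ± 7.45 TPM), Sall4 (234 ± 29.5 against 279 ± 71.9 TPM) and Eomes (22.9 ± 8.73 against 10.5 ± 2.25 TPM) were not called. Both groups carried a large Rn45s share, and their spread between libraries was among the widest, at 0.77 (Epi) and 0.72 (PrE) log2. Fitted alone with genes at 0 left out, a setting chosen after the data were seen, these 6 libraries gave 2029 called genes, array weights gave 2920 and E4.75 in place of E4.5 gave 2646. camera then called 1 of 26 lists in the 6 libraries alone, naive pluripotency (adjusted p = 0.036). The primitive endoderm (0.080), distal and anterior (0.21), secretory (0.24) and cholesterol (0.16) lists were not called there, and the planned fit of these libraries ended the call of Etv5 (limma adjusted p = 0.056).

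At E5.25 secreted endoderm products were far higher in PrE (n = 3 each). Spink1, a protease inhibitor, was 4520.1 ± 356 against 0.225 ± 0.389 TPM (log2 11.89 ± 0.46, adjusted p = 7.7e-28), Apoa1 2538 ± 147 against 0.673 ± 0.405 TPM (log2 10.59 ± 0.51) and Pga5 3336 ± 159 against 0.310 ± 0.537 TPM (log2 11.39 ± 0.42). Ttr (chromosome 18, 20665280 to 20674321) was 1380.5 ± 113 TPM against listed at 0 in Epi (adjusted p = 2.6e-40). Pdgfra was 7.45 ± 0.645 against 0.0126 ± 0.0217 TPM (log2 3.06 ± 0.33, adjusted p = 5.0e-11). limma called 1547 genes higher and 1736 lower in PrE.

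All 20 primitive endoderm genes tested rose (camera adjusted p = 2.2e-10), with Srgn 1956 ± 69.7 against 0.0624 ± 0.108 TPM, log2 10.85 ± 0.38 and Sox17 73.6 ± 6.27 against 0.0684 ± 0.118 TPM, log2 6.13 ± 0.34. Gata6 was 16.3 ± 0.693 TPM against listed at 0. In the visceral endoderm secretory list 13 of 16 rose (adjusted p = 3.3e-09), including the apolipoprotein Apom (918 ± 94.5 TPM against listed at 0). In the distal and anterior visceral endoderm list 10 of 11 rose (adjusted p = 1.1e-07): the Nodal antagonist gene Cer1 (chromosome 4, 82881751 to 82885148) was 61.6 ± 6.31 TPM against listed at 0, the LIM factor Lhx1 52.0 ± 3.60 TPM against listed at 0 and Dkk1 142 ± 1.43 against 0.0425 ± 0.0737 TPM, log2 7.10 ± 0.26. These counts were identical when adjusted over each list alone. Of the developmental regulators 7 of 26 rose and 1 fell (adjusted p = 0.066). Mixl1 was 184 ± 15.3 against 2.98 ± 0.814 TPM, log2 5.56 ± 0.56. Gbx2 fell (0.0484 ± 0.0838 against 3.61 ± 1.19 TPM, log2 -2.10 ± 0.55). Of the naive and giant cell lists, Tbx3 (9.21 ± 1.22 against 0.0583 ± 0.101 TPM, log2 3.27 ± 0.32) rose and Hand1 (8.13 ± 2.79 against 52.9 ± 12.3 TPM, log2 -2.58 ± 0.33) fell. BMP targets rose in 3 of 6 (adjusted p = 0.066). Id1 was 492 ± 44.1 against 101 ± 3.56 TPM, log2 2.28 ± 0.31.

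Core pluripotency genes fell in 7 of 10 cases (adjusted p = 1.6e-04) and formative and primed genes in 8 of 14, with 1 risen (adjusted p = 0.0015). Pou5f1 was 0.107 ± 0.185 against 125 ± 21.3 TPM, log2 -6.83 ± 0.40, Tdgf1 0.281 ± 0.244 against 315 ± 13.6 TPM, log2 -7.96 ± 0.21 and the kinase gene Pim2 19 ± 4.04 against 999.5 ± 154 TPM, log2 -5.65 ± 0.32. The WNT effector Lef1 (listed at 0 against 29.2 ± 2.07 TPM), Fgf4 (listed at 0 against 27.2 ± 10.0 TPM) and Nanog (listed at 0 against 4.49 ± 1.80 TPM) were listed at 0 in PrE. The naive list, called at E4.5, had 4 risen and 4 fallen of 15 (adjusted p = 0.74). The DNA methylation list fell in 4 of 9 (adjusted p = 0.0076), the de novo methyltransferases Dnmt3a (8.03 ± 0.446 against 72.3 ± 4.30 TPM, log2 -3.02 ± 0.18) and Dnmt3b (134 ± 4.39 against 532 ± 109.8 TPM, log2 -1.96 ± 0.22) among them. Dusp6 (22.3 ± 2.13 against 166 ± 25.7 TPM, log2 -2.83 ± 0.21), Phc1 (3.18 ± 0.834 against 68.1 ± 15.1 TPM, log2 -4.05 ± 0.40) and the pyruvate kinase Pkm (1509.8 ± 105 against 3714 ± 187 TPM, log2 -1.30 ± 0.13) also fell. Slc2a3 (230.1 ± 11.9 against 7.42 ± 1.61 TPM, log2 4.79 ± 0.29) and Eomes (38.5 ± 1.33 against 14.6 ± 1.93 TPM, log2 1.35 ± 0.24) rose. Otx2 (85.0 ± 9.55 against 74.0 ± 2.55 TPM), Fgf5 (131 ± 8.69 against 107 ± 5.10 TPM), Zfp42 (62.0 ± 3.70 against 67.5 ± 13 TPM) and Msmo1 (327 ± 11.8 against 174 ± 6.59 TPM) were not called. Of 4 blood genes 2 fell, and of 4 uterine stroma genes 2 fell and 1 rose. Hba-a2, a globin gene with a near-identical copy (0.0678 ± 0.117 against 13.2 ± 4.03 TPM, log2 -3.70 ± 0.51), Dcn (listed at 0 against 2.84 ± 0.517 TPM) and Des (listed at 0 against 2.68 ± 0.257 TPM) were lower in PrE. camera on these 6 libraries alone called 3 of 26 lists, the endoderm lists above.

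The lineage difference itself changed between E4.5 and E5.25, again with unsuffixed Epi, for 2471 genes (limma interaction, 1532 up and 939 down). The PrE minus Epi difference of Dusp6 moved by 2.78 ± 0.30 log2 (adjusted p = 3.0e-10), that of Sox17 by 3.14 ± 0.48 (adjusted p = 1.1e-06) and that of Msmo1 by -1.76 ± 0.29 (adjusted p = 5.8e-06). Nanog and Ttr were also called and are given no fold, as Nanog was listed at 0 in PrE at both ages and Ttr in Epi of E5.25. All these values include the E4.5 libraries with the large Rn45s share. At the ages between, limma called 1353 genes higher and 1293 lower in PrE of E4.75, and 1817 and 1991 at E5.0.

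Cultured Epi of E5.5 was set against E4.5 (n = 3 each). Naive pluripotency genes fell. Zfp42, a marker of naive cells, went to 16.1 ± 6.80 against 746 ± 50.1 TPM (log2 -5.52 ± 0.24, adjusted p = 9.9e-26), Nr0b1 to 1.37 ± 2.38 against 458 ± 80.8 TPM (log2 -8.04 ± 0.50, adjusted p = 1.3e-19) and Dppa5a to 455 ± 46.6 against 8541 ± 1034 TPM (log2 -4.22 ± 0.09). The POU factor Pou3f1 rose to 52.7 ± 6.70 against 1.19 ± 1.23 TPM (log2 4.8 ± 0.33, adjusted p = 9.3e-18), and Dnmt3b to 490.2 ± 31.5 against 58.9 ± 17.3 TPM (log2 3.08 ± 0.22, adjusted p = 2.2e-17). limma called 3491 genes higher and 2212 lower at E5.5, a split that became 2663 and 2737 under median-ratio scaling and 2776 and 2835 with Rn45s left out. The all-gene median was 0.11 log2, and -0.04 after either.

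All 15 naive genes tested fell (camera adjusted p = 8.0e-11; 15 when adjusted over the list alone). Tcl1 was listed at 0 against 153 ± 25.6 TPM. Nanog was 65.5 ± 6.23 against 250.3 ± 63.3 TPM, log2 -1.89 ± 0.43, and lower still at E4.75 and E5.25. Its call was lost with a pseudocount of 0.1 TPM (limma adjusted p = 0.051). Of the formative and primed list 8 of 14 rose, which did not pass as a list (adjusted p = 0.13; 0.045 under median-ratio scaling). The TEAD factor Tead2 (75.2 ± 2.16 against 9.23 ± 2.88 TPM, log2 2.94 ± 0.27) was among them. Trophectoderm genes fell in 6 of 14 (adjusted p = 0.017). Tspan8 was listed at 0 against 61.6 ± 30.7 TPM. Nodal pathway genes rose in 5 and fell in 1 of 10 (adjusted p = 0.41). The antagonist Lefty1 (38.9 ± 9.17 against 5.92 ± 5.71 TPM, log2 3.12 ± 0.42; 2.04 log2 without Epi replicate 2 of E4.5) rose. Its mean in Epi of E5.5 in vivo was below that of E4.5. Nodal itself was 22.7 ± 3.49 against 58.3 ± 5.67 TPM, log2 -1.33 ± 0.44 (adjusted p = 0.011), a call that array weights (0.051) and a pseudocount of 0.1 TPM (0.22) ended. Polarity genes rose in 4 of 10 (adjusted p = 0.41), such as the tight junction gene Cgn (114 ± 34.0 against 1.52 ± 1.26 TPM, log2 5.65 ± 0.39) and Crb3 (175 ± 17.6 against 15.3 ± 3.73 TPM, log2 3.46 ± 0.41). FGF targets rose in 3 and fell in 1 of 8 (adjusted p = 0.41). Spry2 was 471 ± 163 against 3.89 ± 0.847 TPM, log2 6.55 ± 0.42.

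Among chromatin genes, the demethylases Kdm6b (122 ± 15.7 against 4.42 ± 1.48 TPM, log2 4.53 ± 0.33) and Kdm1a (187 ± 13 against 16.8 ± 8.57 TPM, log2 3.52 ± 0.26) rose, 4 of 9 in their list (adjusted p = 0.41). Polycomb genes went 7 up and 7 down of 29 (adjusted p = 0.81), with the methyltransferase Ezh2 129 ± 6.08 against 12.7 ± 7.60 TPM, log2 3.45 ± 0.27 and Phc1 90.2 ± 14.8 against 332 ± 30.9 TPM, log2 -1.88 ± 0.40. DNA methylation genes went 3 up and 3 down of 9 (adjusted p = 0.81). Dnmt3l was 1.79 ± 0.523 against 859.5 ± 88.2 TPM, log2 -8.28 ± 0.39 and Tet2 1.10 ± 0.722 against 42.8 ± 8.69 TPM, log2 -4.42 ± 0.30. Glycolysis genes went 6 up and 2 down of 16 (adjusted p = 0.56): Hk2 was 115 ± 3.56 against 2.91 ± 1.94 TPM, log2 5.05 ± 0.29, Pfkp 11.9 ± 5.33 against 178 ± 27.6 TPM, log2 -3.87 ± 0.33 and Gapdh 806 ± 49.5 against 2476 ± 212 TPM, log2 -1.62 ± 0.12. The cholesterol list had 8 risen and 1 fallen of 18 (adjusted p = 0.41). Insig1 was 229 ± 138 against 24.2 ± 8.37 TPM, log2 3.08 ± 0.37 and Hmgcs1 182 ± 33.4 against 24.8 ± 8.96 TPM, log2 2.88 ± 0.38. Gdf3 (3.28 ± 0.373 against 103 ± 9.19 TPM, log2 -4.61 ± 0.34), the secreted Spp1 (15.2 ± 5.68 against 3447 ± 579 TPM, log2 -7.78 ± 0.30) and Sox17 (listed at 0 against 6.41 ± 4.39 TPM) fell. The splicing gene Arglu1 (1442 ± 244 against 1.92 ± 0.747 TPM, log2 8.97 ± 0.34), Mixl1 (21.2 ± 6.15 against 0.240 ± 0.416 TPM, log2 4.18 ± 0.56) and Prl3d1, a placental lactogen with near-identical neighbours (139 ± 54.6 against 5.45 ± 4.83 TPM, log2 4.92 ± 0.85), rose. Pou5f1 (90.3 ± 8.39 against 181 ± 46.0 TPM), Utf1 (1249.8 ± 106 against 2304 ± 438 TPM) and Dnmt3a (101 ± 9.96 against 59.0 ± 12.3 TPM) were not called. With E4.75 in place of E4.5, chosen after the data were seen, the count fell to 3468, and camera on these 6 libraries alone called 1 of 26 lists, naive pluripotency. The planned fit of the 6 libraries also ended the call of Lefty1 (limma adjusted p = 0.066). By single steps, limma called 2140 genes higher and 2627 lower from ICM to Epi of E4.5. The later steps gave 2483 and 1342 to E4.75, 218 and 966 to E5.0, 589 and 302 to E5.25, and 1077 and 757 to E5.5 in vitro. Under quantile normalization these 5 steps gave 2276 and 2473, 2064 and 1778, 334 and 796, 548 and 440, and 933 and 892.

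The same interval in the primitive endoderm lineage ended in cultured VE of E5.5 (n = 3 each). Mixl1 was 1373 ± 31.9 against 1.31 ± 2.27 TPM (log2 9.66 ± 0.56, adjusted p = 1.3e-20), Lhx1 295 ± 35.2 against 4.94 ± 1.20 TPM (log2 5.65 ± 0.30, adjusted p = 5.3e-22) and the homeobox gene Gsc 71.4 ± 14.7 TPM against listed at 0. Afp, alpha-fetoprotein, was 103 ± 11.1 against 0.213 ± 0.369 TPM (log2 6.46 ± 0.56, adjusted p = 3.7e-14). limma called 4146 genes higher and 1204 lower. That split was 2369 and 2141 under quantile normalization and 3118 and 1733 under median-ratio scaling. The all-gene median was 0.32 log2, and -0.06 after quantile normalization.

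The visceral endoderm secretory list rose in 14 of 16, 14 when adjusted over the list alone (camera adjusted p = 4.6e-04), with fibrinogen beta Fgb 73.1 ± 10.7 against 0.929 ± 1.61 TPM, log2 5.56 ± 0.32 and the retinol carrier Rbp4 109.8 ± 19.1 TPM against listed at 0. All 8 FGF and ERK targets rose (adjusted p = 0.0014), including Spry2 (298 ± 19.4 against 1.71 ± 2.15 TPM, log2 7.07 ± 0.42) and Dusp6 (38.6 ± 2.54 against 0.119 ± 0.206 TPM, log2 5.16 ± 0.21). BMP targets rose in 5 of 6 (adjusted p = 0.0025). Id3 was 488 ± 47.7 against 10.8 ± 8.48 TPM, log2 5.66 ± 0.27 and Id1 401 ± 20.9 against 30.7 ± 6.85 TPM, log2 3.69 ± 0.31. Demethylase genes rose in 7 of 9 (adjusted p = 0.047): Kdm6b was 193 ± 13.2 against 1.72 ± 2.00 TPM, log2 6.42 ± 0.33 and Kdm5b 48.4 ± 0.412 against 3.02 ± 1.88 TPM, log2 3.76 ± 0.24. Polarity genes rose in 8 of 10 (adjusted p = 0.038). Cgn was 189 ± 9.76 against 4.16 ± 3.20 TPM, log2 5.39 ± 0.39 and the integrin Itgb1 98.9 ± 15.7 against 10.4 ± 5.74 TPM, log2 3.23 ± 0.38. The Polycomb list had 16 risen and 3 fallen of 29 (adjusted p = 0.27). Ezh2 was 115 ± 16.3 against 12.8 ± 9.62 TPM, log2 3.27 ± 0.27. Developmental regulators rose in 9 of 26 (adjusted p = 0.12). Msx1 was 246 ± 52.6 TPM against listed at 0. The WNT antagonist Sfrp1 (303 ± 11.1 against 0.416 ± 0.289 TPM, log2 7.77 ± 0.55), Slc2a3 (3146 ± 217 against 86.3 ± 22.7 TPM, log2 5.20 ± 0.29) and Krt18 (2296 ± 158 against 52.8 ± 7.85 TPM, log2 5.42 ± 0.15) also rose.

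The primitive endoderm list went 5 up and 6 down of 20 (adjusted p = 0.34). Sox17 rose (175 ± 43.3 against 49.9 ± 9.97 TPM, log2 1.78 ± 0.34), and Sox7 (57.1 ± 3.81 against 443 ± 33.5 TPM, log2 -2.93 ± 0.39), Sparc (419.9 ± 36.1 against 2123 ± 39.9 TPM, log2 -2.34 ± 0.16) and the laminin Lama1 (9.69 ± 0.841 against 57.1 ± 6.19 TPM, log2 -2.44 ± 0.32) fell. Cholesterol genes fell in 8 and rose in 3 of 18 (adjusted p = 0.12). Fdft1 was 89.7 ± 5.01 against 950.0 ± 43.1 TPM, log2 -3.39 ± 0.18 and Msmo1 148 ± 3.39 against 779.9 ± 118 TPM, log2 -2.38 ± 0.20. Dnmt3l (0.806 ± 0.445 against 171 ± 9.62 TPM, log2 -6.60 ± 0.39), Dppa5a (189.6 ± 15.8 against 3259.8 ± 251 TPM, log2 -4.10 ± 0.09), Lefty1 (8.74 ± 0.930 against 62.3 ± 5.29 TPM, log2 -2.70 ± 0.42) and Nupr1 (listed at 0 against 156 ± 7.77 TPM) fell. The histone genes H3c13 (3.43 ± 2.02 against 624 ± 275 TPM), H3c14 (0.831 ± 0.0666 against 533 ± 212 TPM) and H3c15 (0.902 ± 0.468 against 587 ± 248 TPM) fell as well, and as near-identical copies they are uncertain singly. Pdgfra was 11.6 ± 0.110 against 5.52 ± 2.80 TPM, log2 1.05 ± 0.33 (adjusted p = 0.0073). That call was lost without PrE replicate 3 (0.69 log2, limma adjusted p = 0.12), under quantile normalization (0.64) and median-ratio scaling (0.10), with a pseudocount of 0.1 TPM (0.14) and in these 6 libraries alone (0.11). Pou5f1 was 1.10 ± 0.665 against 7.17 ± 6.21 TPM, log2 -1.35 ± 0.40 (adjusted p = 0.0054; -2.53 log2 without PrE replicate 2). It lost its call without PrE replicate 1 (-0.76 log2, adjusted p = 0.15) or replicate 3 (-0.75 log2, adjusted p = 0.16), with a pseudocount of 0.1 TPM (0.28) and in the planned fit of the 6 libraries (0.45). Eomes rose (72.2 ± 6.31 against 22.9 ± 8.73 TPM, log2 1.69 ± 0.24), while Gata6 (24.0 ± 2.08 against 14.9 ± 4.30 TPM), Hhex (63.3 ± 4.5 against 100.1 ± 13.2 TPM) and Dkk1 (74.8 ± 8.71 against 75.4 ± 4.53 TPM) were not called. With E4.75 in place of E4.5 the count was 3000. camera on the 6 libraries alone called 0 of 26 lists, with 2 at an unadjusted p under 0.05. By single steps, limma called 2106 genes higher and 3412 lower from ICM to PrE of E4.5. The later steps gave 2538 and 836 to E4.75, 157 and 470 to E5.0, 432 and 206 to E5.25, and 2036 and 556 to VE of E5.5. Under quantile normalization these 5 steps gave 2572 and 2789, 1623 and 1255, 222 and 347, 377 and 250, and 930 and 913.

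The trophectoderm derivative that stays diploid, cultured ExE of E5.5, was compared with TE of E3.5 (n = 3 each). Dppa3 (chromosome 6, 122626410 to 122630272), a maternal and germline factor, was listed at 0 against 6203 ± 264 TPM (adjusted p = 3.0e-29), and the homeobox gene Crxos was 0.511 ± 0.628 against 5077 ± 381 TPM (log2 -11.79 ± 0.55, adjusted p = 9.7e-25). Ldha rose to 1809.8 ± 124 against 3.51 ± 1.25 TPM (log2 8.68 ± 0.12, adjusted p = 1.4e-48) and the imprinted RNA H19 to 1199 ± 38.6 against 0.642 ± 0.468 TPM (log2 9.55 ± 0.32, adjusted p = 7.7e-31). Bmp4, which ExE signals to the epiblast with, was 319 ± 19.2 against 0.610 ± 0.425 TPM (log2 7.67 ± 0.61, adjusted p = 1.6e-15). limma called 3819 genes higher and 1734 lower. That split was 2355 and 2345 under quantile normalization and 2912 and 2075 under median-ratio scaling, with an all-gene median of 0.27 log2 in the main values.

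The extra-embryonic ectoderm list rose in 9 of 10 (camera adjusted p = 6.7e-05; 9 when adjusted over the list alone), with Bmp8b (42.4 ± 9.39 TPM against listed at 0) and Rhox6 (41.0 ± 6.69 TPM against listed at 0). Trophoblast giant cell genes rose in 6 of 10 (adjusted p = 0.076). Hand1 was 138 ± 11.3 against 0.218 ± 0.378 TPM, log2 6.87 ± 0.33 and Prl3d1 45.6 ± 10.2 TPM against listed at 0. Glycolysis genes rose in 12 of 16 (adjusted p = 0.0028). Slc2a1 was 411 ± 63.9 against 13.7 ± 3.62 TPM, log2 4.83 ± 0.21 and Pfkp 44.4 ± 3.58 against 0.377 ± 0.118 TPM, log2 5.04 ± 0.33. Oxidative phosphorylation genes fell in 5 of 17 (adjusted p = 0.026; 0.059 under quantile normalization), Cox5a being 824 ± 16.3 against 2974 ± 93.8 TPM, log2 -1.85 ± 0.12 and Cox4i1 904 ± 48.7 against 2900.3 ± 39.5 TPM, log2 -1.68 ± 0.13. Cholesterol genes rose in 16 of 18 (adjusted p = 0.0034). Cyp51 was 76.3 ± 10.8 against 3.46 ± 1.21 TPM, log2 4.14 ± 0.30 and Sqle 209.8 ± 25.6 against 12.3 ± 0.937 TPM, log2 3.98 ± 0.34. FGF targets rose in 7 of 8 (adjusted p = 0.0042). Spry4 was 27.6 ± 1.75 against 0.195 ± 0.338 TPM, log2 4.62 ± 0.34 and Etv5 32.1 ± 5.30 against 0.818 ± 0.502 TPM, log2 4.21 ± 0.40. p53 targets rose in 9 of 11, and 10 when adjusted over the list alone (adjusted p = 0.0028): Btg2, an antiproliferative gene, was 98.3 ± 9.22 against 5.94 ± 1.85 TPM, log2 3.87 ± 0.39, and Phlda3 148 ± 47.8 against 9.89 ± 1.45 TPM, log2 3.73 ± 0.30. ExE of E5.5 in vivo held Btg2 at 9.07 ± 0.214 and Phlda3 at 8.56 ± 8.57 TPM (n = 2).

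Trophectoderm genes fell in 7 and rose in 3 of 14 (adjusted p = 0.017): Tspan8 was 1.45 ± 1.92 against 776 ± 31.3 TPM, log2 -8.60 ± 0.51, Krt8 409 ± 19.8 against 4053 ± 152 TPM, log2 -3.31 ± 0.28 and Cdx2 6.77 ± 5.33 against 30.4 ± 4.99 TPM, log2 -2.21 ± 0.48, the last losing its call with a pseudocount of 0.1 TPM (limma adjusted p = 0.060). Core pluripotency genes fell in 6 and rose in 3 of 10 (adjusted p = 0.022). Pou5f1 was listed at 0 against 87.3 ± 13.2 TPM, and naive genes fell in 7 and rose in 3 of 15 (adjusted p = 0.0034). Nanog was 0.0754 ± 0.0678 against 70.1 ± 8.81 TPM, log2 -6.04 ± 0.43 and Dppa5a 236 ± 4.34 against 11296 ± 729 TPM, log2 -5.58 ± 0.09. Dppa1 was listed at 0 against 578 ± 26.1 TPM. Formative genes rose in 9 of 14 (adjusted p = 0.0059). Pou3f1 was 119 ± 10.0 TPM against listed at 0. Cyp26a1, a retinoic acid-degrading enzyme (811 ± 45.7 TPM against listed at 0), and Id1 (87.0 ± 3.33 TPM against listed at 0) rose. Eomes rose (116 ± 10.1 against 44.3 ± 5.21 TPM, log2 1.37 ± 0.24) and Gata6 fell (3.05 ± 1.97 against 23.6 ± 2.48 TPM, log2 -2.70 ± 0.33). Krt18 (2605 ± 352 against 4904 ± 110.1 TPM) and Zfp42 (364 ± 21.2 against 237 ± 10.3 TPM) were not called. Primitive endoderm genes rose in 16 of 20 (adjusted p = 0.003) and visceral endoderm secretory genes in 11 of 16 (adjusted p = 0.0028), such as Ttr (90.3 ± 10.4 TPM against listed at 0), Apom (97.0 ± 4.43 against 0.742 ± 0.253 TPM, log2 5.82 ± 0.33), Srgn (97.8 ± 12.8 against 1.34 ± 0.316 TPM, log2 5.40 ± 0.38) and Sox17 (14.4 ± 5.41 against 1.34 ± 0.557 TPM, log2 2.68 ± 0.34). Across 34 VE genes under 1 TPM in ExE and Epi in vivo, cultured ExE held a median of 11.8% of the cultured VE level. camera on the 6 libraries alone called 0 of 26 lists, with 9 at an unadjusted p under 0.05. By single steps, limma called 506 genes higher and 2855 lower from TE of E3.5 to E4.5, 2993 and 283 from there to ExE of E4.75, and 2311 and 1085 from there to E5.5. Quantile normalization gave 1187 and 1291, 965 and 880, and 1403 and 1490, with all-gene medians moved from -0.26, 0.40 and 0.17 log2 to about 0.

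The polyploid trophoblast giant cells were set against the extra-embryonic ectoderm at E5.5 in vitro (n = 4 and 3). Prl3d1 (chromosome 13, 27094190 to 27100258), placental lactogen I, reached 109216 ± 6850.5 against 45.6 ± 10.2 TPM (log2 11.22 ± 0.79, adjusted p = 1.3e-17). Its near-identical copies Prl3d2 (23196 ± 984 against 11.4 ± 2.34 TPM) and Prl3d3 (9877 ± 935 against 4.10 ± 0.461 TPM) rose too, and reads shared between the copies leave each level uncertain. The cathepsin Cts7 was 2604 ± 218 against 0.773 ± 0.203 TPM (log2 10.52 ± 0.28, adjusted p = 5.4e-36), and the glycoprotein Psg22, from a family of close paralogs, 1882 ± 169 against 0.423 ± 0.179 TPM. limma called 977 genes higher and 4909 lower in TGC. The split was 2048 and 2197 under quantile normalization and 2105 and 2356 under median-ratio scaling. The all-gene median was -0.51 log2, and 0.01 after quantile normalization.

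The trophoblast giant cell list rose in 7 and fell in 1 of 10, the same counts when adjusted over the list alone (camera adjusted p = 5.9e-06). The receptor Flt1 was its fallen member (listed at 0 against 2.43 ± 0.900 TPM). Hand1 (233 ± 12.3 against 138 ± 11.3 TPM), Gata3 (844 ± 142 against 590.4 ± 55.9 TPM) and Krt18 (4481 ± 164 against 2605 ± 352 TPM) were not called. All 14 mitosis genes fell (adjusted p = 1.7e-04), among them the kinases Plk1 (12 ± 3.82 against 312 ± 46.8 TPM, log2 -4.63 ± 0.16) and Aurkb (4.54 ± 1.14 against 119.8 ± 13 TPM, log2 -4.47 ± 0.25) and the motor Kif11 (3.90 ± 1.10 against 121 ± 8.60 TPM, log2 -4.66 ± 0.33). The cell cycle inhibitor Cdkn1a (chromosome 17, 29090976 to 29100727) rose (622 ± 52.2 against 58.8 ± 7.62 TPM, log2 3.39 ± 0.43). All 6 BMP targets fell (adjusted p = 1.7e-04). Id2 was 4.97 ± 1.89 against 1044 ± 96.6 TPM, log2 -7.50 ± 0.20 and Id1 0.790 ± 0.503 against 87.0 ± 3.33 TPM, log2 -5.67 ± 0.29. Extra-embryonic ectoderm genes fell in 8 of 10 (adjusted p = 3.6e-04). Bmp4 was 0.941 ± 0.858 against 319 ± 19.2 TPM, log2 -7.48 ± 0.57. Wnt7b (0.961 ± 0.452 against 112 ± 29.0 TPM, log2 -5.86 ± 0.53), Eomes (25.3 ± 4.20 against 116 ± 10.1 TPM, log2 -2.16 ± 0.23) and Cdx2 (0.0287 ± 0.0574 against 6.77 ± 5.33 TPM, log2 -2.71 ± 0.45) were lower. Trophectoderm genes went 5 up and 6 down of 14 (adjusted p = 0.15; median 0.64, mean -0.23), with Gata2 228 ± 21.7 against 6.17 ± 1.95 TPM, log2 5.03 ± 0.52. Parietal endoderm genes went 2 up and 1 down of 8 (adjusted p = 0.15), with Thbd, thrombomodulin, 143 ± 21.5 against 0.320 ± 0.440 TPM, log2 6.81 ± 0.24. The uterine stroma list, with 4 kept members and no list test, had 1 risen, Des, the muscle filament desmin (67.8 ± 2.34 against 4.86 ± 1.84 TPM, log2 3.60 ± 0.39).

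Cholesterol genes fell in 15 of 18 (adjusted p = 0.0053). Sqle was 17.8 ± 0.448 against 209.8 ± 25.6 TPM, log2 -3.48 ± 0.32. Glycolysis genes fell in 11 and rose in 1 of 16 (adjusted p = 0.014; 0.058 under median-ratio scaling), with Slc2a3 0.968 ± 0.506 against 457 ± 43.7 TPM, log2 -7.90 ± 0.28 and Pfkl 23.6 ± 4.30 against 292 ± 44.3 TPM, log2 -3.58 ± 0.17. FGF targets fell in 7 of 8 (adjusted p = 0.024). Dusp6 was 4.64 ± 0.764 against 141 ± 16.6 TPM, log2 -4.66 ± 0.20. Core (7 of 10, adjusted p = 0.0089) and formative genes (10 of 14, adjusted p = 0.014) fell, with Dppa4 1.58 ± 0.702 against 414 ± 43.4 TPM, log2 -7.36 ± 0.29 and Pou3f1 0.412 ± 0.406 against 119 ± 10.0 TPM, log2 -6.45 ± 0.31. Polarity genes fell in 6 of 10 (adjusted p = 0.13), with the cadherin Cdh1 2.11 ± 1.03 against 109 ± 12.8 TPM, log2 -5.20 ± 0.27 and Crb3 1.14 ± 1.22 against 75.7 ± 4.60 TPM, log2 -5.33 ± 0.38. Polycomb genes fell in 16 and rose in 1 of 29 (adjusted p = 0.12). Cyp26a1 fell (1.01 ± 1.00 against 811 ± 45.7 TPM, log2 -8.77 ± 0.30). Primitive endoderm genes were lower in 18 of 20 (adjusted p = 3.6e-04) and visceral endoderm secretory genes in 12 of 16 (adjusted p = 5.7e-04). Dab2 was 1.10 ± 0.724 against 513 ± 46.0 TPM, log2 -7.99 ± 0.27, Apoe 15 ± 6.96 against 1512 ± 138 TPM, log2 -6.66 ± 0.15, Sox17 0.0197 ± 0.0395 against 14.4 ± 5.41 TPM, log2 -3.85 ± 0.32, Gata6 0.0453 ± 0.0906 against 3.05 ± 1.97 TPM, log2 -1.85 ± 0.31 and Ttr listed at 0 against 90.3 ± 10.4 TPM. Cultured ExE, the other side here, held a median of 11.8% of the VE level over 34 VE genes. Pdgfra (1.21 ± 0.496 against 2.93 ± 2.15 TPM) was not called. camera on the 7 libraries alone called 2 of 26 lists, giant cell genes and mitosis. At E4.75 limma called 330 genes higher and 348 lower in TGC, and from E4.75 to E5.5 in vitro 1022 rose and 2301 fell within TGC.

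The effect of culture was assessed in the epiblast at E5.5 (n = 3 in vitro, 2 in vivo). Lefty1 was 38.9 ± 9.17 against 0.163 ± 0.231 TPM (log2 5.09 ± 0.47, adjusted p = 3.5e-12), Id1 104 ± 16.3 against 3.53 ± 3.60 TPM (log2 4.79 ± 0.35, adjusted p = 1.3e-15) and the p53 target Sesn2 44.6 ± 13.7 against 2.08 ± 0.997 TPM (log2 3.88 ± 0.50, adjusted p = 3.0e-08). Nanog was 65.5 ± 6.23 against 6.66 ± 8.81 TPM (log2 3.89 ± 0.49, adjusted p = 1.0e-08; 2.25 log2 without in vivo replicate 2). Dppa5a was lower, at 455 ± 46.6 against 4121 ± 108 TPM (log2 -3.18 ± 0.10, adjusted p = 1.9e-30), as was Dnmt3a, at 101 ± 9.96 against 427 ± 61.3 TPM (log2 -2.07 ± 0.20, adjusted p = 6.5e-12). limma called 2344 genes higher and 1047 lower in vitro. The split was 1561 and 1622 under quantile normalization and 1694 and 1455 under median-ratio scaling, with an all-gene median of 0.18 log2 in the main values.

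p53 targets rose in 9 of 11 (camera adjusted p = 0.004; 9 when adjusted over the list alone), including Bbc3, a pro-apoptotic gene (6.58 ± 3.70 TPM against listed at 0), and the receptor gene Eda2r (7.02 ± 2.68 against 0.576 ± 0.815 TPM, log2 2.39 ± 0.49). Bax (797 ± 74.4 against 451 ± 107 TPM) and Zmat3 (6.52 ± 1.46 against 5.09 ± 2.07 TPM) were not called. Nodal pathway genes rose in 8 of 10 (adjusted p = 0.038). Nodal was 22.7 ± 3.49 against 3.10 ± 4.38 TPM, log2 3.13 ± 0.49 (1.71 log2 without in vivo replicate 2). BMP targets rose in 3 of 6 (adjusted p = 0.0051). Id3 was 431 ± 7.86 against 96.8 ± 23.9 TPM, log2 2.17 ± 0.31. Extra-embryonic ectoderm genes rose in 4 of 10 (adjusted p = 0.042). Immediate early and heat shock genes rose in 9 of 13, 10 when adjusted over the list alone (adjusted p = 0.059). Fos was 52.2 ± 9.24 against 7.60 ± 0.602 TPM, log2 2.62 ± 0.39 and Atf3 6.14 ± 2.31 TPM against listed at 0. Cholesterol genes rose in 10 and fell in 1 of 18 (adjusted p = 0.089). Lss was 31.9 ± 1.5 against 4.31 ± 5.34 TPM, log2 3.14 ± 0.42 and Mvd 114 ± 28.2 against 21.1 ± 29.8 TPM, log2 4.10 ± 0.59. Without in vivo replicate 2 these were 1.86 and 1.38 log2, and Mvd was 6.82 without replicate 1. Oxidative phosphorylation genes rose in 4 of 17 (adjusted p = 0.091). Cyp26a1 (41.4 ± 2.91 against 0.0467 ± 0.0661 TPM, log2 5.34 ± 0.36) rose, as did Prl3d1 (139 ± 54.6 TPM against listed at 0), a giant cell gene. Pou5f1 was 90.3 ± 8.39 against 25.2 ± 4.89 TPM, log2 1.81 ± 0.45 (adjusted p = 0.0016), a call lost with a pseudocount of 0.1 TPM (limma adjusted p = 0.10). Cox5a (849 ± 60.7 against 390.0 ± 79.7 TPM, log2 1.13 ± 0.13) dropped under 1 log2 without Epi in vivo replicate 2 (0.92) and under median-ratio scaling (0.85).

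DNA methylation genes fell in 2 of 9 (adjusted p = 0.004). Dnmt3l was 1.79 ± 0.523 against 26.1 ± 10.5 TPM, log2 -3.24 ± 0.43, while Dnmt3b (490.2 ± 31.5 against 982 ± 147 TPM) was not called. Visceral endoderm secretory genes fell in 7 and rose in 1 of 16 (adjusted p = 0.004). Ttr was 0.368 ± 0.323 against 14.6 ± 0.987 TPM, log2 -3.54 ± 0.24, Fgb 0.0380 ± 0.0658 against 11.9 ± 4.24 TPM, log2 -3.59 ± 0.35 and Apoa1 1.84 ± 1.26 against 26.7 ± 14.9 TPM, log2 -3.29 ± 0.57. VE_Epi in vivo, the neighbouring tissue, held Ttr at 818 ± 148 and Fgb at 462 ± 30.3 TPM. Klf4 (0.524 ± 0.488 against 8.15 ± 3.19 TPM, log2 -2.60 ± 0.41), Pou3f1 (52.7 ± 6.70 against 202 ± 8.20 TPM, log2 -1.92 ± 0.37), Lef1 (30.5 ± 6.0 against 114 ± 37.0 TPM, log2 -1.84 ± 0.34) and Fgf4 (10.1 ± 3.44 against 36.2 ± 4.92 TPM, log2 -1.79 ± 0.35) fell. Dppa3 was 1.87 ± 1.62 against 54.7 ± 2.83 TPM, log2 -4.51 ± 0.52. The topoisomerase Top2a (165 ± 10.4 against 859 ± 135 TPM, log2 -2.37 ± 0.25) fell, with mitosis genes 2 up and 2 down of 14 (adjusted p = 0.53). Demethylases had 2 fallen of 9 (adjusted p = 0.11), Kdm6a among them (7.39 ± 1.85 against 31.2 ± 2.93 TPM, log2 -1.96 ± 0.36), and Polycomb genes 3 risen and 6 fallen of 29 (adjusted p = 0.51). Jarid2 was 27.3 ± 7.45 against 83.8 ± 1.42 TPM, log2 -1.61 ± 0.31. Of 4 uterine stroma genes 2 rose and 1 fell, the proteoglycan Dcn (0.371 ± 0.548 against 20.9 ± 8.01 TPM, log2 -4.02 ± 0.46), and of 4 blood genes 1 rose. Both lists were too short for a test. Rpl39l (listed at 0 against 77.7 ± 5.23 TPM), close in sequence to Rpl39, and Rpgrip1 (28.1 ± 3.11 against 1036 ± 142 TPM, log2 -5.16 ± 0.82) also fell. Fitted alone with genes at 0 left out, chosen after the data were seen, these 5 libraries gave 1505 called genes and array weights 1850. In that fit Nodal (limma adjusted p = 0.056), Eda2r (0.059) and Mvd (0.11) were not called. The planned fit of the 5 libraries called 777 genes. It also ended the calls of Nanog (limma adjusted p = 0.13), Lss (0.13), Apoa1 (0.084), Bbc3 (0.077), Fgf4 (0.065), Klf4 (0.064), Dppa3 (0.058), Jarid2 (0.051) and Lef1 (0.051). In the fit without genes at 0 camera called 0 of 26 lists, with 4 at an unadjusted p under 0.05.

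In ExE of E5.5, transcripts of the endoderm were higher in vitro than in vivo (n = 3 in vitro, 2 in vivo). Dab2 was 513 ± 46.0 against 3.65 ± 1.86 TPM (log2 6.85 ± 0.33, adjusted p = 5.6e-23), Spink1 686 ± 81.4 against 6.70 ± 8.08 TPM (log2 7.05 ± 0.51, adjusted p = 1.3e-15) and Ttr 90.3 ± 10.4 against 0.575 ± 0.369 TPM (log2 5.87 ± 0.24, adjusted p = 7.1e-26). The trophoblast factor Elf5 was 147 ± 10.9 against 43.5 ± 0.899 TPM (log2 1.74 ± 0.27, adjusted p = 2.8e-06), and Eomes (116 ± 10.1 against 126 ± 10.9 TPM), Bmp4 (319 ± 19.2 against 281 ± 50.1 TPM) and Cdx2 (6.77 ± 5.33 against 4.30 ± 6.08 TPM) were not called. limma called 1464 genes higher and 378 lower in vitro. The split was 745 and 702 under quantile normalization, with an all-gene median of 0.19 log2 in the main values.

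Primitive endoderm genes were higher in 19 of 20 (camera adjusted p = 5.4e-10), visceral endoderm secretory genes in 9 of 16, 10 when adjusted over the list alone (adjusted p = 2.7e-07), and distal and anterior visceral endoderm genes in 6 of 11, 7 over the list alone (adjusted p = 0.0026). Srgn was 97.8 ± 12.8 against 1.23 ± 1.01 TPM, log2 5.54 ± 0.43, Sox17 (chromosome 1, 4490931 to 4497354) 14.4 ± 5.41 against 0.0200 ± 0.0282 TPM, log2 3.85 ± 0.38 and the collagen chaperone Serpinh1 26.7 ± 3.69 TPM against listed at 0. Gata6 (chromosome 18, 11052064 to 11085635) was 3.05 ± 1.97 TPM against listed at 0 and Pdgfra 2.93 ± 2.15 against 0.00480 ± 0.00679 TPM, log2 1.76 ± 0.36. In these 5 libraries alone neither Gata6 (limma adjusted p = 0.054) nor Pdgfra (0.13) was called, and quantile normalization brought Pdgfra to 0.98 log2. Apom (97.0 ± 4.43 against 0.316 ± 0.447 TPM, log2 6.26 ± 0.37), Apoc2 (91.1 ± 13.9 against 0.647 ± 0.915 TPM, log2 5.92 ± 0.32), Pga5 (142 ± 19.7 TPM against listed at 0), Lhx1 (12.3 ± 2.44 against 0.173 ± 0.245 TPM, log2 3.5 ± 0.34) and Hesx1 (10.8 ± 2.78 TPM against listed at 0) were higher. The 34 genes high in cultured VE and under 1 TPM in ExE and Epi in vivo had median ratios to VE of 13.6%, 12.8% and 9.32% in the 3 cultured ExE libraries.

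**Figure D3:**
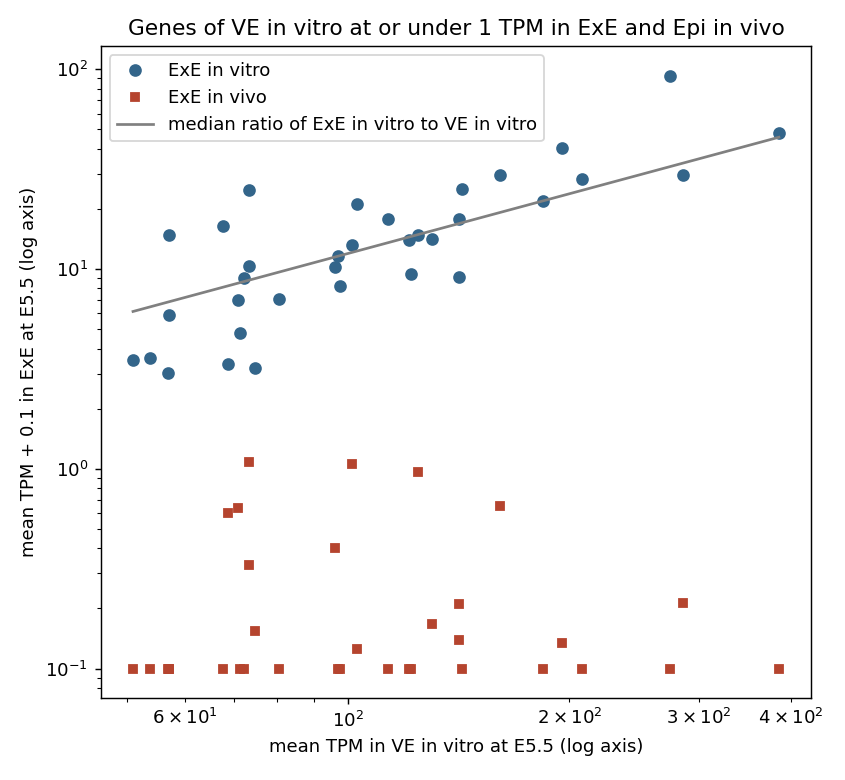
Each point is 1 of 34 visceral endoderm genes, its mean TPM in cultured VE on the horizontal axis and its mean TPM + 0.1 in ExE in vitro or in vivo on the vertical axis, both log scales. The line marks the median ratio of 11.8%, around which the in vitro points scatter from 4.13% to 34.0%.

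p53 targets rose in 10 of 11, all 11 when adjusted over the list alone (adjusted p = 5.4e-08): Phlda3 was 148 ± 47.8 against 8.56 ± 8.57 TPM, log2 4.28 ± 0.34, Cdkn1a 58.8 ± 7.62 against 4.93 ± 0.564 TPM, log2 3.33 ± 0.51 and Btg2 98.3 ± 9.22 against 9.07 ± 0.214 TPM, log2 3.30 ± 0.43. Bbc3 (5.87 ± 5.22 against 0.787 ± 1.11 TPM) was not called. BMP targets rose in 3 of 6, 4 over the list alone (adjusted p = 0.0026). Id3 was 79.4 ± 9.72 against 5.30 ± 2.94 TPM, log2 3.75 ± 0.31 and Id1 87.0 ± 3.33 against 15.9 ± 6.57 TPM, log2 2.44 ± 0.35. DNA methylation genes were called lower as a list (adjusted p = 0.031) with 1 of 9 fallen, Tet3 (1.52 ± 0.694 against 5.21 ± 0.445 TPM, log2 -1.34 ± 0.36). Tet3 lost its call without ExE in vivo replicate 1 (limma adjusted p = 0.063), with a pseudocount of 0.1 TPM (0.12) and in the 5 libraries alone (0.14). Glycolysis genes fell in 2 of 16 (adjusted p = 0.12): Hk2 was 68.0 ± 8.0 against 159.7 ± 1.38 TPM, log2 -1.23 ± 0.32 and Gpi1 151 ± 16.6 against 318 ± 39.8 TPM, log2 -1.07 ± 0.16. Gpi1 came to -0.99 log2 without ExE in vitro replicate 2 and -0.94 without ExE in vivo replicate 2. Krt18 rose (2605 ± 352 against 966 ± 226 TPM, log2 1.44 ± 0.17). Krt8 (409 ± 19.8 against 187 ± 7.85 TPM, log2 1.13 ± 0.31) lost its call without ExE in vivo replicate 1 (0.066), and median-ratio scaling brought it to 0.97 log2. Without the same library Adm (listed at 0 against 5.44 ± 0.888 TPM) was at 0.071 and Top2a (146 ± 6.78 against 315 ± 37.2 TPM, log2 -1.10 ± 0.25) at -0.98 log2. Lef1 (0.0166 ± 0.0287 against 2.32 ± 1.43 TPM, log2 -1.64 ± 0.34) was at 0.056 without ExE in vivo replicate 2. The planned fit of the 5 libraries (631 genes) ended the calls of Lef1 (limma adjusted p = 0.072), Phlda3 (0.069) and Rpgrip1 (0.053). The demethylase Kdm6b (125 ± 4.20 against 260.0 ± 15.2 TPM, log2 -1.05 ± 0.36, adjusted p = 0.041) lost its call without any 1 of the 5 libraries (0.068 to 0.20), with a pseudocount of 0.1 TPM (0.23), without the filter on low values (0.061) and with array weights (0.076). Stfa1 (listed at 0 against 32.4 ± 1.46 TPM), Rpgrip1 (33.6 ± 18.6 against 731 ± 453 TPM, log2 -4.39 ± 0.82) and the small nucleolar RNA Snora31 (13.6 ± 5.45 against 484 ± 21.7 TPM, log2 -5.12 ± 0.67), a short gene whose TPM is uncertain, fell. Fitted alone with genes at 0 left out, the 5 libraries gave 1131 called genes, and camera called 0 of 26 lists, with 4 at an unadjusted p under 0.05. Outside E5.5, limma called 3589 genes higher and 307 lower in unsuffixed than in vivo Epi of E5.0 (1626 and 1331 under quantile normalization), and 1244 and 421 at E5.25 (786 and 668). Cultured VE against both in vivo VE groups gave 3559 and 781 (1762 and 1511).

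The last comparison set visceral endoderm labelled VE_ExE against that labelled VE_Epi, both of E5.5 in vivo (n = 3 and 2). Anterior visceral endoderm genes were lower in VE_ExE. Cer1 was listed at 0 against 204 ± 8.44 TPM (adjusted p = 3.9e-28), Lefty1 listed at 0 against 96.2 ± 5.82 TPM (adjusted p = 4.4e-16) and Otx2 listed at 0 against 121 ± 3.25 TPM (adjusted p = 6.1e-18). Sfrp1 was 5.71 ± 7.26 against 641 ± 68.1 TPM (log2 -7.33 ± 0.62, adjusted p = 1.2e-13). Pdgfra was higher, at 68.4 ± 16.3 against 6.38 ± 0.684 TPM (log2 3.21 ± 0.36, adjusted p = 1.3e-09), as was Phlda2, an imprinted growth regulator, at 285 ± 31.7 against 10.1 ± 7.51 TPM (log2 4.87 ± 0.36, adjusted p = 1.1e-15). limma called 557 genes higher and 1983 lower in VE_ExE, and 897 and 1272 under quantile normalization, which moved the all-gene median from -0.06 to 0.10 log2. These calls rest on a spread shared by all 23 groups, while the VE_ExE libraries varied most among the groups (residual SD 1.03 log2). Fitted alone with genes at 0 left out, a setting chosen after the data were seen, the 5 libraries gave 0 calls by limma at the adjusted threshold, with 1606 genes at an unadjusted p under 0.05. The planned fit of the 5 libraries gave 216 and array weights 791.

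The distal and anterior visceral endoderm list was lower in 10 of 11 (camera adjusted p = 8.8e-09; 10 when adjusted over the list alone; adjusted p = 0.093 in the 5 libraries alone). Gsc was listed at 0 against 45.2 ± 13 TPM and Lhx1 42.0 ± 7.66 against 712 ± 58.3 TPM, log2 -4.07 ± 0.34. Formative genes were lower in 7 and higher in 2 of 14 (adjusted p = 0.049; adjusted p = 0.48 alone), with Fgf5 16.5 ± 16.6 against 146 ± 11.9 TPM, log2 -4.13 ± 0.55 (-2.59 log2 without VE_ExE replicate 2) and Cdh2 0.840 ± 0.827 against 23.1 ± 0.411 TPM, log2 -3.82 ± 0.37. Nodal pathway genes were lower in 4 of 10 (adjusted p = 0.089): Nodal was 1.09 ± 1.81 against 16.8 ± 2.07 TPM, log2 -3.42 ± 0.49 and Foxh1 listed at 0 against 40.6 ± 1.94 TPM. Eomes (9.79 ± 2.07 against 122 ± 22.8 TPM, log2 -3.52 ± 0.27), Mixl1 (86.9 ± 66.7 against 893 ± 145 TPM, log2 -3.59 ± 0.63) and the ephrin Efna5 (4.54 ± 7.86 against 277 ± 63.5 TPM, log2 -6.81 ± 0.60) were lower, and Hoxa10 was listed at 0 against 14.7 ± 3.80 TPM. Mitosis genes were lower in 3 of 14 (adjusted p = 0.4). Plk1 was 119 ± 31.8 against 299.7 ± 58.6 TPM, log2 -1.34 ± 0.19. BMP targets were higher in 2 of 6 (adjusted p = 0.0013; adjusted p = 0.29 alone), with Id2 662 ± 311 against 65.0 ± 10.4 TPM, log2 3.19 ± 0.24 and Id3 171 ± 62.3 against 49.1 ± 18.7 TPM, log2 1.78 ± 0.31. Primitive endoderm genes were higher in 6 and lower in 2 of 20 (adjusted p = 0.049; adjusted p = 0.29 alone). Sox17 (36.9 ± 16.9 against 10.4 ± 0.568 TPM, log2 1.62 ± 0.38) and Sox7 (33.2 ± 4.70 against 10.2 ± 0.143 TPM, log2 1.60 ± 0.43) lost their calls with array weights (limma adjusted p = 0.17 and 0.18) and with a pseudocount of 0.1 TPM (0.058 and 0.23). Tbx3 (126 ± 76.9 against 25.2 ± 2.17 TPM, log2 2.11 ± 0.36) was at 0.060 with array weights. Cholesterol genes were higher in 5 and lower in 1 of 18 (adjusted p = 0.056). Insig1 was 4269.8 ± 2576 against 358 ± 32.2 TPM, log2 3.29 ± 0.41. Secretory genes went 1 up and 4 down of 16 (adjusted p = 0.93): Rbp4 was 112 ± 69.8 against 776 ± 82.6 TPM, log2 -3.01 ± 0.49. Apoc2 (4606 ± 647 against 2069 ± 85.8 TPM, log2 1.15 ± 0.32) was at 0.054 without VE_Epi replicate 1, 0.15 with a pseudocount of 0.1 TPM and 0.41 with array weights, and at 0.92 log2 after quantile normalization. Afp (34.2 ± 43.7 against 87.6 ± 14.4 TPM, log2 -2.39 ± 0.63) was at -1.19 log2 (adjusted p = 0.12) without VE_ExE replicate 3 and lost its call with the smaller pseudocount (0.15). Crabp2 (45.6 ± 5.35 TPM against listed at 0), Igsf11 (107 ± 32.9 against 4.23 ± 0.219 TPM, log2 4.32 ± 0.29), the cell cycle inhibitor Cdkn1c (46.3 ± 19.3 against 2.18 ± 2.68 TPM, log2 4.14 ± 0.54), Pth1r (159 ± 38.1 against 35.1 ± 0.164 TPM, log2 2.11 ± 0.38) and Klf4 (22.5 ± 5.70 against 2.80 ± 0.619 TPM, log2 2.61 ± 0.41) were higher. Gata6 (41.8 ± 16.1 against 33.7 ± 0.569 TPM), Dab2 (836 ± 11.9 against 824 ± 79.2 TPM), Apoe (7526 ± 1138 against 5765 ± 268 TPM), Dkk1 (28.1 ± 12.4 against 49.1 ± 15.6 TPM) and Id1 (86.3 ± 19.6 against 43.1 ± 8.84 TPM) were not called. No list reached the threshold in the 5 libraries alone (camera, 0 of 26, with 3 at an unadjusted p under 0.05).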

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

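The test of a shift of all genes was chosen after the result was seen. Those of carried-over cells and of other sample splits were written beforehand.

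From E4.5 to E5.25 the PrE minus Epi difference changed for 2471 genes (limma interaction). Among named genes the difference moved by 1.66 log2 in Srgn, 3.14 in Sox17, 3.55 in Apoa1, 1.04 in Dkk1, -1.76 in Msmo1, 2.29 in Pga5, -1.73 in Pou5f1, 2.78 in Dusp6 and 3.73 in Phc1. List medians moved by 3.75 for naive pluripotency, 3.14 for visceral endoderm secretory genes, 1.10 for distal and anterior visceral endoderm, 1.46 for trophectoderm, 0.40 for developmental regulators, -1.54 for cholesterol and 2.03 for BMP targets (camera on the interaction). Exchanging libraries between the ages within each lineage gave as many genes in 12 of 100 splits, the real one included, with up to 6297 genes. That count decides nothing about chance, since exchanging more libraries in 1 lineage puts the age difference into the interaction. All 9 with 2 more called 3322 to 4442 genes. Equal exchanges (37, at most 46 genes) mix ages and widen the spread, so they decide nothing either.

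Culture differences at E5.5 differed between Epi and ExE for 1557 genes (limma interaction). The difference of differences was 2.35 log2 in Id1, -1.58 in Id3, -9.41 in Ttr and -1.27 in Top2a. Called genes with a group listed at 0 are given no value in either test. It was -3.5 for the primitive endoderm list, -3.0 for visceral endoderm secretory genes, -1.82 for distal and anterior visceral endoderm and 1.38 for immediate early and heat shock genes (medians).

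The endoderm transcripts in cultured ExE were weighed further. Across 34 visceral endoderm genes the upper quartile of the ExE to VE ratio was 1.85, 1.95 and 2.06 times the lower in the 3 libraries, a narrow range that is consistent with carried-over visceral endoderm cells. A shift of all genes is argued against, since the primitive endoderm list stood 3.29 log2 above the median of all genes after quantile normalization. Expression of these genes by the cultured ExE cells themselves stays open and was not tested.

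Among 35 genes tested in the 4 TGC libraries of E5.5, 2 had a value far from the others, where chance gives about 1 in 20. The values were 0.297 TPM for Wnt7b (replicate 3) and 4235 TPM for Krt18 (replicate 1). Genes above 0 in a single library were left out after the values were seen.

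Only the real split of 35 called as many genes for TGC minus ExE at E5.5 (5886, next 4137) and TGC from E4.75 to E5.5 (3323, next 2010). Mixing groups widens the spread, so chance stays open. Comparisons of 3 against 3 have 10 splits, too few for a share under 0.05. Their highest other splits called 15 genes for TE minus ICM (real 2108), 1456 for PrE minus Epi at E4.5 (4450), 3 at E5.25 (3283), 671 for Epi from E4.5 to E5.5 (5703), 346 for PrE to VE (5350) and 7 for TE to ExE (5553). For every stepwise and other-age comparison of that size, and for unsuffixed against in vivo Epi, the highest other was at most 481.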

How the results depend on the processing

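Chosen after the data were seen were the tests with E4.75 in place of E4.5, Rn45s left out, fits of only the groups compared without genes at 0, and camera in those fits. Median-ratio scaling, the smaller pseudocount, no filter, no minimum difference and Rn45s left out kept all 10 counts of the main comparisons within 1.5 times, and quantile normalization kept 28 of 29 counts (TE of E4.5 to ExE of E4.75 gave 1845). Array weights gave 1850 genes for Epi culture, 2920 for PrE minus Epi at E4.5 and 791 for VE_ExE minus VE_Epi. E4.75 in place of E4.5 gave 3468 for Epi, 2646 for PrE minus Epi and 3000 for VE. Planned fits of only the groups compared gave 3618 for Epi, 777 for Epi culture, 631 for ExE culture, 1767 for PrE minus Epi at E4.5 and 216 for VE_ExE minus VE_Epi. Without genes at 0 they gave 1505, 1131 and 2029 for Epi culture, ExE culture and PrE minus Epi, and 0 for VE_ExE minus VE_Epi (limma, 1606 at an unadjusted p under 0.05). The cause was not tested, except that fewer libraries enter those fits.

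Leaving out 1 library gave 1825 to 1916 genes for TE minus ICM, 4163 to 4583 for PrE minus Epi at E4.5, 2921 to 2967 at E5.25, 5378 to 5778 for Epi, 4921 to 5482 for VE, 5086 to 5307 for ExE and 5523 to 5752 for TGC minus ExE. It gave 2614 to 3397 for Epi culture, 1447 to 1706 for ExE culture, 2114 to 3043 for VE_ExE minus VE_Epi and 1279 to 1734 for the culture interaction. Where a group was left with 1 library, it was assumed to vary like the others. Of 389 gene results retested, 0 reversed under any setting run. Quantile normalization ended 3 calls, median-ratio scaling 4, array weights 6, no filter 1, the smaller pseudocount 13 and fits of only the groups compared 46 (40 without genes at 0). The replicate block in those fits ended 111 (101 without genes at 0), and leaving out 1 library ended calls in 22 of 2254 values. Of 260 list results, camera in those fits ended 57 calls, and a preset correlation added 35. fry, which tests whether a list moves as a whole without comparing it with other genes, passed in the other direction for 8 lists camera did not call. In VE limma's fry gave an adjusted p = 0.00137 for H3K4 methyltransferases, 0.00715 for oxidative phosphorylation, 0.0118 for hypoxia, 0.00060 for p53 targets and 0.00815 for mitosis. In TGC minus ExE they were trophectoderm (0.00837), hypoxia (8.9e-05) and p53 targets (0.00592).

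Pairing by replicate number stays open. No comparison had every same-numbered pair correlated over 0.1, but 2 or 3 pairs decide nothing. With the number as a replicate block in the planned fits, 818 genes were called for PrE minus Epi at E4.5, 2595 for Epi and 2502 for VE. The block gave 2379 and 1938 for the Epi steps to E4.5 and E4.75, then 491, 0 and 420 to E5.0, E5.25 and E5.5. For the PrE steps to E4.5, E4.75 and E5.25 the block gave 3118, 1557 and 235. Without genes at 0 the block gave 2201 for PrE minus Epi, 1128 for PrE from E4.75 to E5.0 and 970 from E5.0 to E5.25. The block called 0 in the 3 comparisons with 2 in vivo libraries in either form (limma, 2640, 2353 and 1089 genes at an unadjusted p under 0.05 in the planned form). Unknown depth limits what can be said of low genes.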

Other observations

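The tests of Rn45s and of E4.75 in place of E4.5 were chosen after the result was seen, while the other tests were written beforehand. p53 targets were higher beyond the E5.5 Epi and ExE comparisons. In unsuffixed against in vivo Epi, 9 of 11 rose at E5.0 (camera adjusted p = 0.00056) and 7 of 11 at E5.25 (9.5e-05), and in cultured VE against both in vivo VE groups 10 of 11 rose (0.00039). In fits of only the groups compared at E5.5 the list was not called in Epi (0.28) or ExE (0.10), and the other comparisons were not tested that way.

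Gene length, GC content and expression level were weighed for the p53 targets. The list median stood at percentile 100 among 10000 matched random lists in Epi (1.66 log2) and in ExE (2.69), which argues against those properties as the cause. In ExE the visceral endoderm share would carry over a median of 0.0847 of the excess, which argues against carried-over cells as its whole cause. A response of the tissue to culture or handling stays open as a hypothesis, and any batch that follows culture cannot be separated from it.

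More genes were higher than lower from Epi of E4.5 to E5.5. With Rn45s left out 49.5% of called genes were higher, and with E4.75 in place of E4.5 49.8%, so the excess is consistent with the composition of the E4.5 libraries. Among genes of at least 50 TPM the share was 60.9%, which leaves weaker detection of low genes undecided. From PrE of E4.5 to VE the same tests gave 69.7%, 66.3% and 64.5%, which argues against each as the whole cause there. Quantile normalization, which removes a shift of all genes by construction, gave 52.5%, so a difference in scale stays open.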
